A study of Mus musculus with 8 samples.

How the data were processed

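Total RNA including small RNA was taken from 30 mg of kidney, and 100 ng was end-labelled with Cy3 and hybridised to a single-colour Agilent mouse miRNA array, per the labels' protocols. All 8 arrays lay on 1 slide read in 1 scan, per the file headers, with sham arrays in slide row 1 and IRI arrays in slide row 2. Slide columns 1 to 4 each held 1 array of either group. Groups and replicate numbers were taken from the sample titles: sham 1, 2, 3 and 6, and IRI 1, 2, 3 and 18.

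The deposited scanner files hold spot intensity on a linear scale, made with Agilent Feature Extraction 12.0.3.1 per the file headers and the submitters' processing notes. Per the file headers, background was taken as a fitted surface and subtracted, spot outliers were marked, and no normalization between arrays was applied. The deposited value table holds a linear ratio per miRNA, and how the authors made it is not given in the sources used here. Set against the scanner files, it matched total gene signals scaled by 1 factor per array and divided by a centre per entry, close to its median over the arrays. A higher ratio means more signal, while the scaling rule and the exact centring stay unknown. Its column medians were 0.859, 1.23, 1.29 and 1.3 for the sham arrays, and 0.658, 0.646, 1.16 and 0.749 for the IRI arrays. It served only as an alternative.

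From 56430 spots of 4415 probes, control spots and spots marked as outliers (1422 to 1560 per array) were left out; 0 spots were saturated. Processed signals were averaged over the spots of a probe and summed over the probes of a miRNA. None of the 185 miRNAs called had a probe whose change opposed the sum. Dim probes were raised to a floor of their own in this check. A probe at that floor on all arrays has a change of 0 and cannot oppose, and miR-1a-3p and miR-487b-3p each had a probe with a change of 0. Each array was divided by its 75th percentile over the 317 miRNAs detected on all 8 arrays, rescaled by the geometric mean of these percentiles. Values were then raised to a floor of 17.3, the 5th percentile of scaled signals over detected miRNAs, and taken to log2. The log2 change of a miRNA that lies at the floor in one group is no measured size and can be too small or too large. The lowest scaled signal among miRNAs well above background was 23.9 to 27.6 on sham arrays and 17.8 to 19.6 on IRI arrays. Both ranges lie above the floor, and the sham range lies farther above it. Where a miRNA was detected on no array of a group, the fold is given as "at least": the mean of the bright group against, per array, the higher of the miRNA's own signal and the lowest signal among miRNAs well above background. The 379 miRNAs detected on all 4 arrays of at least 1 group were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg, threshold 0.05), with no covariate. The named miRNAs follow a rule set before the data were examined: the 8 largest rises and 8 largest falls among calls detected on all 8 arrays without overlap between groups, the 4 largest bounds per direction, up to 3 of the brightest tested members of each list, and 8 fixed miRNAs. Lists, tests and most alternatives were also set before the data were examined. Other miRNAs named, among them miR-132-3p, miR-141-3p, miR-200c-3p, miR-18a-5p, miR-93-5p, miR-106b-5p, miR-188-5p, miR-32 and miR-652, were chosen after their values were seen.

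The 21 lists were tested with camera (preset correlation 0.01, Benjamini-Hochberg over lists with at least 3 tested members), and with an estimated correlation and fry as alternatives. Array measures and clustering were compared with exact permutation tests over the 35 splits of 8 arrays, and correlations of arms with 100000 permutations. The fit was tested on simulated data for IRI against sham with 379 miRNAs at the observed means and spreads. It recovered 10 of 20 miRNAs changed 1.5-fold, 18 of 20 changed 2-fold and 20 of 20 changed 4-fold, with 2 calls among 319 unchanged miRNAs. The simulated miRNAs were independent of each other and did not pass through scaling, floor or filter, so those steps were not tested. No 2 arrays held duplicate data. Alternatives covered scaling, background correction, the value per miRNA, filters, the floor, the variance model, blocks and leaving out each array. Scaling to the labelling spike-ins, the tests of array measures within slide columns, the tests of arm differences and the comparison of neighbouring miRNA genes were added after seeing the data. A genome and annotation of build mm9 were not used here. Of the tested miRNAs, 334 of 379 matched a gene name in the GRCm38.p6 RefSeq table, which was used for names and neighbourhood only.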

Results

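The data are 8 mouse kidney samples, 4 from mice with ischemia-reperfusion injury (IRI) and 4 from sham-operated mice, each hybridised to 1 single-colour miRNA microarray. IRI is a model of acute kidney injury: the right kidney is removed and the blood supply of the left kidney is clamped and then released. Sham mice had a midline incision only and kept both kidneys, so the groups differ by nephrectomy as well as by injury. Per the series' design text, the males were C57BL/6 mice aged 9 weeks, the clamp lasted 25 or 45 min, and kidneys were taken 12 or 24 h later. The labels do not say which IRI sample had which clamp time or harvest time, so the 4 IRI samples are treated as 1 group. They also do not say that each sample is a separate animal, so p-values measure only the spread between these samples. The arrays carried probes for 1881 mouse miRNAs. Of these, 478 were detected on at least 1 array and 317 on all 8. Precision is limited by the number of arrays, 4 per group.

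The first comparison asked whether the arrays of both groups gave similar overall signal. IRI arrays had 421 ± 22.1 detected miRNAs (SD, n = 4) and sham arrays 358 ± 22.2 (SD, n = 4), a difference of 63 miRNAs (exact permutation test, two-sided, p = 0.0286, the smallest p that the 35 splits of 8 arrays allow; 0.2 after Benjamini-Hochberg adjustment over the 7 array measures compared). Without sham replicate 2 or sham replicate 6 the p of the exact test was 0.0571. The 75th percentile of signal, over miRNAs detected on all 8 arrays, was 500 ± 55.9 (SD, n = 4) in IRI and 406 ± 49.8 (SD, n = 4) in sham (exact permutation test, two-sided, p = 0.0571). Each of the 4 slide columns held 1 array of either group, and within every column IRI was higher, by 76.1 to 122 in the percentile and by 26 to 94 detected miRNAs. Taken within columns, a comparison added after seeing the data, both differences had a p of 0.125 (exact sign-flip test, two-sided), the smallest that 16 sign flips allow. The 2 spike-in RNAs added before labelling differed less: the log2 ratio of IRI to sham was 0.05 for one and -0.09 for the other, with exact permutation p of 0.286 and 0.171. The 10 brightest miRNAs held 71.8% ± 2.32 of the total signal in IRI and 74% ± 0.485 in sham (SD, n = 4).

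The main comparison, IRI against sham, asked which kidney miRNAs changed after injury. Rises included those of miR-21a, an miRNA induced in injured and inflamed tissue, of miR-223-3p, which is abundant in neutrophils and other myeloid cells, and of the red blood cell miRNAs miR-451a and miR-144-3p. miR-21a-5p was 2.76-fold higher in IRI (log2 change 1.47 ± 0.16, SE; adjusted p = 0.00063, limma), with scaled signals of 20222 ± 4672 in IRI and 7180 ± 408 in sham (SD, n = 4). The opposite arm of the same precursor, miR-21a-3p, was detected on all 4 IRI arrays and on 0 of 4 sham arrays, and was at least 13.1-fold higher in IRI (adjusted p = 6.68e-07, limma). miR-223-3p was 2.88-fold higher (log2 change 1.53 ± 0.15, SE; adjusted p = 0.00049, limma). miR-451a was 11.5-fold higher (log2 change 3.53 ± 0.86, SE; adjusted p = 0.011, limma), with sham signals that spread from 42.8 to 835. Its log2 change was 2.65 without sham replicate 1 and 4.08 without sham replicate 3, and it stayed called without any 1 array. That call ended when all 1881 miRNAs were tested (adjusted p = 0.126, limma).

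Among 379 miRNAs detected on every array of at least 1 group, 46 were higher and 139 lower in IRI at an adjusted p below 0.05 (limma, Benjamini-Hochberg), relative to the 75th percentile of each array. Most falls were small. Their median was -0.43 on the log2 scale. The fitted change reached 2-fold for 1 of the 139 falls and for 20 of the 46 rises. These 20 include miRNAs at the floor on most or all sham arrays, such as miR-21a-3p and miR-132-3p, whose fitted change is no measured size. Detection on all 8 arrays held for 136 of the falls but for 29 of the rises, so the sizes are not compared alike. The direction of the imbalance in calls depended on the scaling between arrays. Without scaling, 53 miRNAs were higher and 1 lower, and with scaling to the labelling spike-ins, an alternative chosen after seeing the data, 75 were higher and 2 lower. The median log2 change of the tested miRNAs was -0.11 with the main scaling, 0.17 without scaling and 0.18 with the spike-ins. Falls below are therefore falls relative to the rest of the array. The 4 IRI values lay entirely above the 4 sham values for 40 miRNAs and entirely below for 136, where chance gives 2.86% of miRNAs in the 2 directions together.

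**Figure D1:**
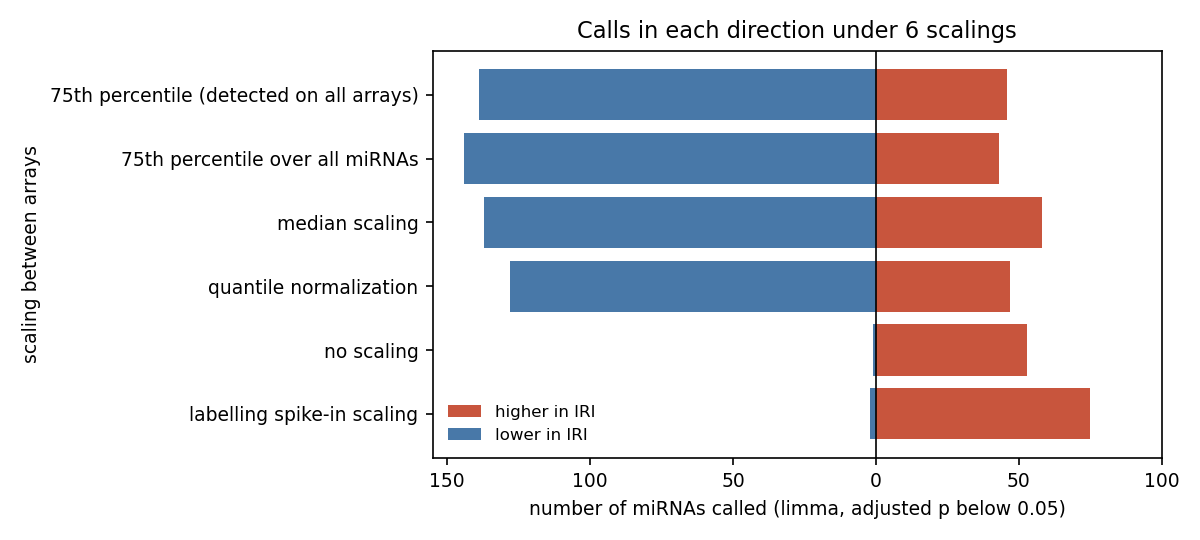
The number of miRNAs called higher (right) or lower (left) in IRI at an adjusted p below 0.05 (limma), for 6 ways of scaling the arrays. The main scaling gave 46 higher and 139 lower, no scaling 53 and 1, and the labelling spike-ins 75 and 2.

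Among miRNAs detected on all 8 arrays with no overlap between groups, the largest rises after miR-451a were those of miR-6931-5p (5.22-fold, log2 change 2.38 ± 0.21, SE), miR-3082-5p (3.28-fold), miR-7036a-5p (2.93-fold), miR-223-3p, miR-21a-5p, miR-574-5p (2.56-fold) and miR-1187 (2.55-fold). Their adjusted p ranged from 0.0004 for miR-6931-5p to 0.0012 for miR-1187 (limma). The largest falls were those of miR-192-3p (fell by 1.03 ± 0.09 on the log2 scale, SE), miR-3968 (0.76), miR-193a-3p (0.74), miR-365-3p (0.72), miR-194-5p (0.71), miR-185-5p (0.71), miR-192-5p (0.69) and miR-107-3p (0.69). Without scaling, miR-192-3p alone of these 8 remained called (log2 change -0.72, adjusted p = 0.014, limma), and the spike-in scaling also left miR-3968 (-0.44, adjusted p = 0.046, limma). None of the 8 turned direction under any scaling tried. The size of the miR-192-3p fall is less certain, since its signal on IRI arrays lay near the floor. Its 2 probes changed by -0.96 and -0.16, but dim probes were raised to a floor of their own. These probe changes therefore need not be measured sizes. Across 24 other settings the log2 change of miR-192-3p ranged from -1.14 to -0.34, and it stayed called. In addition to miR-21a-3p, bounds for miRNAs detected on all 4 IRI arrays and no sham array were at least 2.73-fold for miR-7040-5p, at least 1.47-fold for miR-486a-5p and at least 1.29-fold for miR-466h-5p. The call of miR-466h-5p was lost and its sign turned with normexp background correction (log2 change -0.11, adjusted p = 0.335, limma), and the call ended in 11 of 23 other settings. That of miR-7040-5p ended in 3 of 23 (adjusted p up to 0.098, limma). No miRNA was detected on all 4 sham arrays and 0 IRI arrays.

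**Figure D2:**
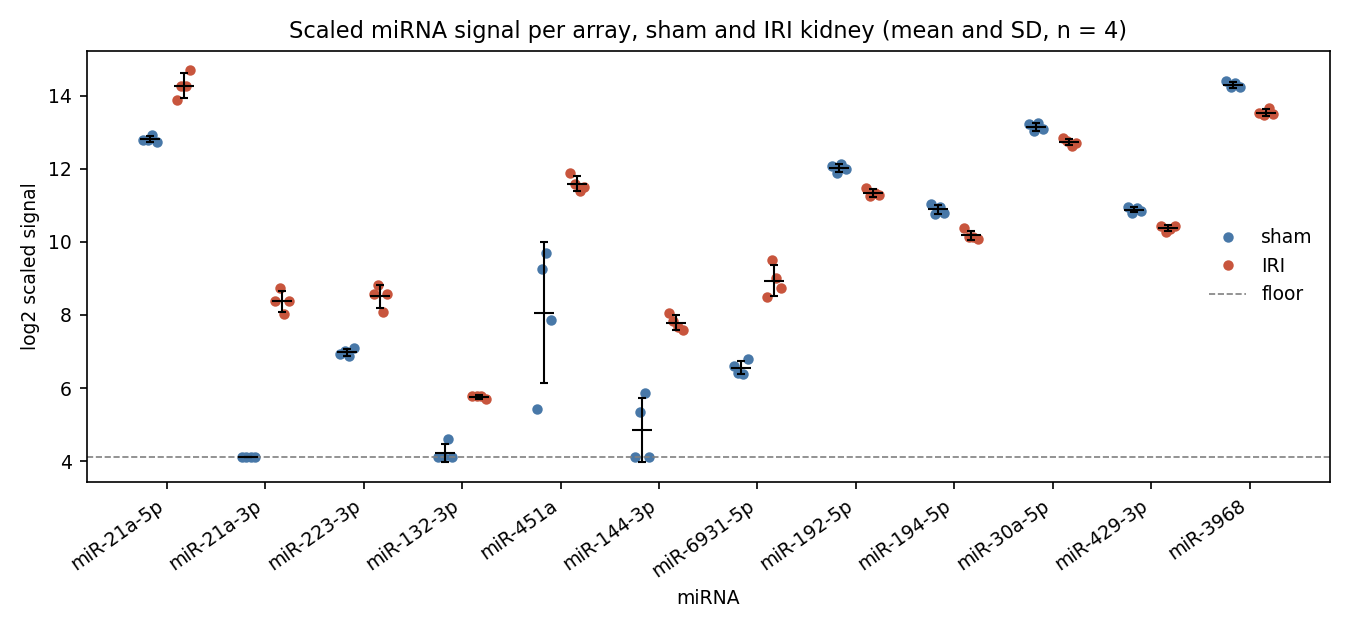
Log2 scaled signal (vertical axis) of 12 miRNAs on each sham (blue) and IRI (red) array. Bars are means with SD (n = 4) and the dashed line is the floor of 4.11. miR-21a-3p is at the floor on all 4 sham arrays, and the sham values of miR-451a spread more widely than its IRI values.

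Most kidney tubule miRNAs fell relative to the array. Of 17 tested members, 15 were lower, 0 higher and 2 not called, with a median log2 change of -0.42; adjusted over the list alone, 16 were lower. As a set the list passed camera (adjusted p = 0.000136), but not with an estimated correlation (adjusted p = 0.421). The falls was led by both arms of miR-192 and by miR-194-5p, miRNAs abundant in kidney epithelium. miR-192-5p had a signal of 4164 ± 317 in sham and 2586 ± 182 in IRI (SD, n = 4), a log2 change of -0.69 ± 0.08 (SE; adjusted p = 0.00075, limma). miR-30a-5p fell by 0.42 ± 0.08 and miR-30c-5p by 0.45 ± 0.08 on the log2 scale (SE). Without scaling the list median was -0.12 and 1 member was called. The let-7 family behaved alike, with 10 of 12 lower and a median of -0.42 (10 adjusted over the list alone; camera adjusted p = 0.421 with an estimated correlation): let-7a-5p fell by 0.46, let-7f-5p by 0.49 and let-7c-5p by 0.43. Without scaling its median was -0.12 and 0 members were called.

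Of the miR-200 family, which marks epithelial cells, 5 of 7 tested members were lower (5 adjusted over the list alone; median -0.38). miR-429-3p fell by 0.50, miR-200a-3p by 0.46 and miR-200b-3p by 0.45 on the log2 scale, whereas miR-200c-3p had a change of 0.10 ± 0.08 and miR-141-3p of -0.06 ± 0.08 (SE), neither called. Of the miR-29 family, whose known targets include collagen and other matrix genes, 4 of 5 were lower (4 adjusted over the list alone; median -0.49). miR-29c-3p fell by 0.57, miR-29b-3p by 0.49 and miR-29a-3p by 0.40, the last turning to 0.05 with quantile normalization. Of the endothelial list 2 members were tested, both arms of miR-126a, and both were lower, miR-126a-3p by 0.32 (turning to 0.13 with quantile normalization) and miR-126a-5p by 0.37. Of 6 fibroblast and mural miRNAs, 3 were lower (6 adjusted over the list alone; median -0.41), and as a set they were not called by camera (adjusted p = 0.152): miR-143-3p fell by 0.43 and miR-199b-5p by 0.51 (a call lost in 16 of 24 other settings), while miR-199a-3p had a change of -0.37 ± 0.15 (SE) and was not called. The muscle miRNA miR-1a-3p fell by 0.54. Without scaling, 0 members of the miR-200, miR-29, endothelial, fibroblast and muscle lists were called.

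Red blood cell miRNAs were all higher: 3 of 3 tested members were called, and 3 adjusted over the list alone (median log2 change 2.93; camera adjusted p = 0.376 with an estimated correlation). miR-144-3p, made from the same cluster as miR-451a, was 7.64-fold higher, with detection on 2 of 4 sham arrays, so this size rests partly on values at the floor. The third member, miR-486a-5p, was detected on no sham array and lost its call with normexp background correction (log2 change 0.11, adjusted p = 0.235, limma). Of 6 tested miRNAs of inflammatory signalling, 3 were higher and 1 lower (3 and 1 adjusted over the list alone; camera adjusted p = 0.376 with an estimated correlation). The risers were both arms of miR-21a and miR-132-3p, which was detected on 1 of 4 sham arrays, so that its fitted log2 change of 1.53 is no measured size, and miR-212-3p fell by 0.54, a call lost without scaling. miR-146a-5p had a change of -0.53 ± 0.25 (SE) and was not called. Of 5 leukocyte miRNAs, miR-223-3p alone was called (1 adjusted over the list alone). miR-142a-3p, found across blood cell types, had a log2 change of 0.29 ± 0.16, and miR-342-3p of -0.14 ± 0.13 (SE), which turned to 0.17 without scaling. The lymphocyte miRNA miR-150-5p had a change of -0.57 ± 0.21 (SE; adjusted p = 0.0566, limma). The hypoxia-inducible miR-210-3p had a change of -0.21 ± 0.13 (SE; adjusted p = 0.223, limma), which turned to 0.10 without scaling. It was called lower with the percentile over all miRNAs, with quantile normalization and with normexp background correction.

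**Figure D3:**
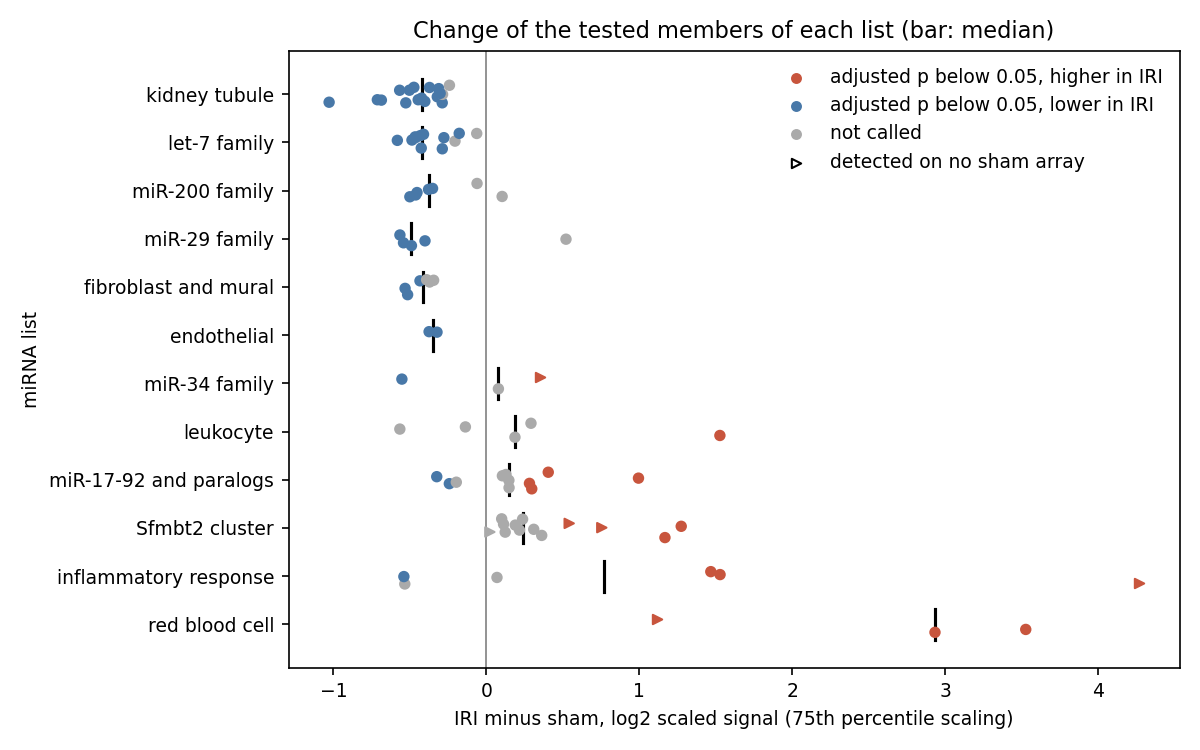
Log2 change of IRI minus sham (horizontal axis) for each tested member of 12 miRNA lists, coloured by call (limma, adjusted p below 0.05), after scaling to the 75th percentile; black bars are list medians and triangles mark miRNAs detected on no sham array, whose plotted change is no bound. The 3 red blood cell miRNAs lie to the right, and the kidney tubule members all lie below 0. Without scaling between arrays the kidney tubule median is -0.12.

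The miR-17-92 cluster and its paralogs, linked to proliferation, split: 4 of 11 tested members were higher and 2 lower (4 and 2 adjusted over the list alone; camera adjusted p = 0.546 with an estimated correlation). miR-18a-5p was 1.99-fold higher and miR-20a-5p rose by 0.30 on the log2 scale, while the paralogs miR-93-5p and miR-106b-5p fell by 0.32 and 0.24; without scaling those 2 falls were not called. With the spike-ins 8 members were higher and 0 lower, and with the percentile taken over all miRNAs 1 was higher and 3 were lower. miR-19b-3p had a change of 0.13 and miR-20b-5p of 0.10, neither called, and the percentile over all miRNAs turned miR-20b-5p to -0.0036. In the miR-34 family, a set regulated by p53, miR-34a-5p fell by 0.55 (a call lost without scaling), miR-34c-5p was called higher with detection on 0 of 4 sham arrays but gave no bound above 1-fold, and miR-34b-5p had a change of 0.08, which turned to -0.02 with quantile normalization (1 higher and 1 lower adjusted over the list alone). Of the Sfmbt2 list, 4 of 13 tested members were higher and 0 lower (4 and 0 adjusted over the list alone; camera adjusted p = 0.421 with an estimated correlation). These included miR-466i-5p, 2.42-fold higher, whose gene overlaps Cdk13 rather than Sfmbt2 in the RefSeq table. miR-669p-3p had a change of 0.10, which turned to -0.01 with quantile normalization, and miR-467f, whose gene overlaps Fxr2, of 0.12, neither called. Of 3 tested Dlk1-Dio3 miRNAs, miR-487b-3p fell by 0.51 (1 adjusted over the list alone, and 0 called without scaling), whereas miR-494-3p at -0.06 and miR-370-3p at 0.01 were not called, and the signs of both turned under other scalings. The nervous system miRNAs miR-9-5p and miR-9-3p had changes of 0.13 and 0.16 and were not called.

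Entries with 4-digit numbers in the miRNA catalogue, many of them rich in G and C, had 20 of 150 tested members higher and 18 lower (16 and 15 adjusted over the list alone; median 0.17; camera adjusted p = 0.421 with an estimated correlation). They were 43.5% of the miRNAs called higher and 39.6% of those tested. The balance of these counts depended on the processing: 28 were higher and 0 lower without scaling, 42 and 1 with the spike-ins, and 9 and 22 with normexp background correction. The 3 brightest were miR-6366, which fell by 0.54, miR-5100, which fell by 0.51, and miR-3963, with a change of -0.26 that was not called and turned to 0.04 without scaling. Entries matching ribosomal or transfer RNA were not called: miR-712-5p had a change of -0.21 ± 0.08 (SE), which turned to 0.09 without scaling, and miR-714 was detected on 0 of 4 sham arrays. Of miRNAs recalled from the kidney injury literature, 7 of 28 tested were higher and 11 lower (7 and 13 adjusted over the list alone), with a median of -0.29 and a mean of 0.05, which differ in sign; without scaling 7 were higher and 1 lower and the median turned to 0.02. The liver miRNA miR-122-5p was detected on 1 IRI array and 0 sham arrays and was not tested, and 0 of the 8 pancreas arms were detected on any array.

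As sets against the other miRNAs, 7 of the 14 lists with at least 3 tested members passed camera with a preset correlation of 0.01. The kidney tubule (adjusted p = 0.000136) and let-7 lists (0.00228) were shifted down. The high-number (5.94e-07), Sfmbt2 (0.00465), red blood cell (0.00527), inflammatory (0.0385) and miR-17-92 lists (0.0411) were shifted up. With an estimated correlation none of the 7 calls held: adjusted p = 0.421 for the kidney tubule, let-7, Sfmbt2 and high-number lists, adjusted p = 0.376 for the red blood cell and inflammatory lists, and adjusted p = 0.546 for miR-17-92. Of 24 other settings, the miR-17-92 call ended in 13 (adjusted p up to 0.285) and the inflammatory call in 11 (up to 0.534). The let-7 and Sfmbt2 calls ended in 1 each, the latter when all 1881 miRNAs were tested (adjusted p = 0.0647). The kidney tubule and high-number calls held in all 24, and the red blood cell call in the 23 that left it at least 3 tested members. fry asks whether members shift from 0 rather than from the other miRNAs. With fry in place of camera, the kidney tubule list was called (adjusted p = 0.000759) but the high-number list was not (adjusted p = 0.43). Lists called down by fry and not by camera were miR-200 (adjusted p = 0.00603), miR-29 (0.0318) and fibroblast (0.0486). With quantile normalization the let-7 (adjusted p = 0.155), inflammatory (0.059) and miR-17-92 (0.205) calls ended. Without sham replicate 6 the inflammatory list had an adjusted p of 0.0763 and miR-17-92 of 0.0828, and without IRI replicate 3 they had 0.0593 and 0.0672. Without IRI replicate 2 miR-17-92 had an adjusted p of 0.0553. The miR-200, fibroblast, miR-29, leukocyte, miR-34, Dlk1-Dio3 and literature lists were not called by camera. When all 1881 miRNAs were tested, most of them detected on no array, camera did call the miR-200 (adjusted p = 7.74e-05), miR-29 (9.76e-05), fibroblast (0.000506) and literature lists (0.0256), and the endothelial list with 4 members (0.0365), all shifted down.

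The series title names a clustering analysis, and the arrays clustered by group. Pearson's r over the 379 tested miRNAs, which are not independent replicates, averaged 0.992 within sham, 0.987 within IRI and 0.965 between groups. The within-group minus between-group difference of 0.0253 was the largest of the 35 splits (exact permutation test, one-sided, p = 0.0286, the smallest it allows), and an average-linkage tree divided into 2 branches separated the groups. The 379 miRNAs were selected by detection in the real groups and kept for all splits, which can favour the real split. Clustering on the 317 miRNAs detected on all 8 arrays alone was not tested. Sham arrays lay in one row of the slide and IRI arrays in the other, so slide row and group cannot be told apart.

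Both arms of a precursor were compared as a check within the data. Across 38 precursors with both arms tested, the 5p and 3p log2 changes correlated at r = 0.63 (permutation p = 6e-05) and rho = 0.64 (permutation p = 2e-05). Precursors are not independent replicates. Without the 2 precursors farthest from the median on the 5p axis r was 0.48. With the series value table in place of the scanner values r was 0.295 and no longer passed the threshold (permutation p = 0.0532).

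In the array's own annotation, on genome build mm9, the miR-21a-5p probes match chromosome 11 from 86397588 to 86397607 and the miR-21a-3p probes from 86397631 to 86397645. The miR-451a probes match chromosome 11 from 77886689 to 77886709, miR-223-3p chromosome X from 93438225 to 93438244, and miR-192-5p chromosome 19 from 6264860 to 6264877. miR-194-5p probes match 2 places, on chromosome 1 from 187137210 to 187137225 and on chromosome 19 from 6264664 to 6264679, so its signal cannot be assigned to 1 precursor. By name in the GRCm38.p6 RefSeq table, the miR-21a gene overlaps Vmp1 and the miR-192 gene overlaps no other listed gene. Exon or intron placement was not analysed here. Probes of near-identical family members, such as those of let-7 and miR-30, can bind each other's miRNA, so values of single members are uncertain.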

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

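The tests of array scaling, tubule cell share, base composition, signal near the floor and RNA fragments were chosen after the results they bear on were seen, as were scaling to the labelling spike-ins and the comparisons of arms and of neighbouring genes, and the tests of blood, a single array and other splits before.

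Among named miRNAs, 8 of 129 groups of 4 arrays held 1 array far from the other 3, where chance gives about 1 in 20 groups. Another 11 groups with values at the floor were not tested, since such values have no order. On the log2 scale, miR-185-5p was 7.853 on IRI replicate 1 against 7.68 to 7.681 on the other IRI arrays. IRI replicate 3 stood apart for miR-210-3p at 4.446 (others 4.949 to 5.039), miR-29a-3p at 11.78 (others 12.15 to 12.17) and miR-29b-3p at 11.33 (others 11.65 to 11.69). miR-342-3p was 7.025 on sham replicate 6, with the other sham arrays at 6.79 to 6.821. miR-126a-3p was 12.13 on sham replicate 2, with the others at 12.32 to 12.33. miR-199b-5p stood apart in both groups, at 7.793 on sham replicate 1 (others 8.037 to 8.066) and at 6.908 on IRI replicate 18 (others 7.62 to 7.692).

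More miRNAs were called lower than higher in IRI, 139 against 46, after scaling to the 75th percentile. Under scaling to the labelling spike-ins 2.6% of calls were falls, so the imbalance may come from the scaling, and whether miRNA as a share of total RNA rose in IRI stays open. A smaller share of tubule cells as the whole cause would raise the markers of other cell types alike. The red blood cell list changed by 2.87 more than the endothelial list (log2, SE 0.489), whose own change was -0.35 (SE 0.07). The leukocyte list changed by 0.609 more than the endothelial list (SE 0.133), or 0.293 (SE 0.148) without miR-223-3p. These contrasts cannot decide the question, since they were chosen after the list changes were seen. Red blood cell miRNAs may also follow the amount of blood. The first measure tried, fibroblast and mural minus tubule, was 0.0331 (SE 0.160). A smaller share of tubule cells, a change in blood or leukocyte content, slide row and injury stay open.

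The median log2 change of the 150 tested high-number entries lay 0.46 above that of the other tested miRNAs (bootstrap interval 0.37 to 0.56). However, the list's camera call did not hold with an estimated correlation (adjusted p = 0.421). fry did not call the list (adjusted p = 0.43), but fry asks whether members shift from 0 and so does not bear on the gap. The entries were 43.5% of the miRNAs called higher against 39.6% of those tested. Base composition and length, fitted on the other miRNAs, predicted a gap of 0.13 (bootstrap interval -0.04 to 0.28), so composition could account for much of the gap or for none of it and stays open. A first test of composition and of signal near the floor, on the 20 entries called higher alone, was dropped because those were chosen for rising. Signal near the floor as the whole cause is argued against by a gap of 0.48 among tested miRNAs with a mean signal above the median (bootstrap interval 0.32 to 0.67). The size of the shift still depended on background correction. With normexp the list median was -0.102 and that of all tested miRNAs -0.168, against 0.172 and -0.113 with the main processing. A part played by low signal therefore stays open. The list of entries matching ribosomal or transfer RNA had a median change of 0.0399 over 2 members that went opposite ways, so fragments of such RNA stay open, as do slide row and injury.

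All 3 tested red blood cell miRNAs were higher in IRI. Across the IRI arrays the SD of miR-144-3p minus miR-451a was 0.338 of the SD of miR-451a (0.0704 against 0.208), so the pair moved together, as they might with a varying amount of retained blood. Of the other tested miRNAs, 5 (1.32%) followed miR-451a as closely. A single IRI array is argued against, since the lowest rise of miR-451a without 1 IRI array was 3.43 on the log2 scale, although it was 2.65 without sham replicate 1. The 2 miRNAs also share a transcript, so the test does not separate blood from a change in that transcript, and slide row stays open.

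The real split of the 8 arrays was the only 1 of 35 to give as large a count in each of 4 tests. That is the smallest share that 35 splits allow, and it was not adjusted for the 4 tests. Chance is therefore made less likely but is not excluded. It gave 185 changed miRNAs, with at most 1 in another split. It gave 10 precursors with unequal arms and 20 unequal neighbouring pairs, with at most 0 in another split, among miRNAs selected with the real groups. It gave 7 lists called by camera, against up to 6 in another split, so the list count stood little above those of other splits, and with an estimated correlation 0 lists were called.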

How the results depend on the processing

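Scaling to the labelling spike-ins and the slide column block on the detected miRNAs per array were chosen after seeing the data. The counts of changed, higher and lower miRNAs moved by over 1.5 times without scaling (54 changed, 1 lower), with the spike-ins (77 changed, 75 higher, 2 lower), with normexp (18 higher), without the detection filter (111, 21 and 90, where 1881 miRNAs are tested) and under the replicate block. Falls made up 75.1% of calls, and 89.8% with normexp, 1.85% without scaling and 2.6% with the spike-ins. Of the 185 calls, 41 were shared without scaling, where 20 changed sign, and 47 with the spike-ins, where 22 did. Called lists numbered 4 with quantile normalization and 0 with an estimated correlation, and fry called 9. The arm correlation was 0.295 with the series value table. Apart from scaling and filter, the causes were not tested.

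Signs turned as follows (log2). With the percentile over all miRNAs: mmu-miR-20b-5p -0.003594, mmu-miR-34b-5p -0.02968, mmu-miR-370-3p -0.09921 and mmu-miR-669p-3p -0.008232. With median scaling mmu-miR-370-3p was -0.01569. With quantile normalization: mmu-miR-126a-3p 0.1275, mmu-miR-34b-5p -0.01601, mmu-miR-29a-3p 0.04502, mmu-miR-494-3p 0.2698, mmu-miR-370-3p -0.07032, mmu-miR-669p-3p -0.01465 and mmu-miR-3963 0.08966. Without scaling: mmu-miR-210-3p 0.0965, mmu-miR-342-3p 0.1662, mmu-miR-494-3p 0.2411, mmu-miR-712-5p 0.09335 and mmu-miR-3963 0.03987. With the spike-ins these 5 were, in that order, 0.1135, 0.1832, 0.2581, 0.1103 and 0.05685. With normexp: mmu-miR-466h-5p -0.1134, mmu-miR-34b-5p -0.147, mmu-miR-34c-5p -0.1233, mmu-miR-370-3p -0.168, mmu-miR-669p-3p -0.0631, mmu-miR-467f -0.05384, mmu-miR-9-5p -0.1541, mmu-miR-9-3p -0.1545 and mmu-miR-714 -0.1215, and mmu-miR-486a-5p kept its sign at 0.1142 but lost its call (adjusted p = 0.235). With the brightest probe mmu-miR-494-3p was 0.001717, with the series value table mmu-miR-370-3p was -0.04394, and with array weights it was -0.1145. The causes were not tested.

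Leaving out each array in turn gave 153 to 190 changed miRNAs, 36 to 64 higher, at least 114 lower, 5 to 7 lists, a correlation between the arms of one precursor of 0.5802 to 0.7205, a within-group minus between-group difference in the clustering of the arrays of 0.02222 to 0.02809, and a difference in detected miRNAs per array of 52.75 to 72.25. The latter had an exact permutation p of 0.0571 without sham replicate 2 (63.08) or 6 (52.75). mmu-miR-370-3p ranged from -0.1176 to 0.1135, mmu-miR-494-3p from -0.1546 to 0.03174, mmu-miR-669p-3p from -0.05037 to 0.2801 and mmu-miR-467f from -0.04362 to 0.3128. Of called named miRNAs, mmu-miR-199b-5p lost its call without any 1 of sham replicates 1, 2, 3 and 6 or IRI replicates 2 and 3, and mmu-miR-29a-3p without sham replicate 1 or 3 or IRI replicate 2 or 3. mmu-miR-466h-5p lost its call without any 1 of sham replicates 1, 2 and 6 or IRI replicates 1 and 18, and mmu-miR-143-3p without sham replicate 3.

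The labels do not say that replicate numbers pair the arrays. Deviations of same-numbered arrays correlated at -0.16, -0.20 and 0.24, which are too few values to exclude a pairing. Same-numbered arrays also shared a slide column. Over columns 1 to 4 the median coefficient of variation between spots was 6.00, 5.76, 6.63 and 7.44% on sham arrays. On IRI arrays it was 5.93, 5.76, 6.40 and 7.16%, so spot quality ran alike within columns. With the replicate block, on 3 pairs, 67 miRNAs were changed, 17 higher and 50 lower, on fewer arrays, and mmu-miR-451a lost its call (adjusted p = 0.107). The arrays in slide column 4, whose numbers differ, correlated at 0.50. With the slide column as a block, 49 were higher and 125 lower, and the difference in detected miRNAs per array stayed 63 with an exact p of 0.125, the smallest that 16 sign flips allow. Signal near background limits miRNAs detected in 1 group only.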

Other observations

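The comparisons of arms and of neighbouring miRNA genes were chosen after the data were seen.

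Arms of 1 precursor changed unequally for 10 of 38 precursors (limma on the 3p minus 5p signal, adjusted p below 0.05). For miR-21a the 3p arm rose more than the 5p arm, and since miR-21a-3p was detected on no sham array, the fitted difference is no measured size. The 3p arm of miR-192 fell more than the 5p arm, by 0.34 ± 0.05 on the log2 scale (SE; adjusted p = 0.0025, limma). The 3p arm is far dimmer (3p minus 5p -6.62 in sham and -6.97 in IRI, log2). It lay near the floor on IRI arrays, and its 2 probes, with dim values raised to a floor, changed by -0.96 and -0.16. The size of the difference between the miR-192 arms is therefore uncertain. The arms of miR-32 went opposite ways, miR-32-3p with a log2 change of 0.93 ± 0.23 and miR-32-5p of -0.53 ± 0.09 (SE), with miR-32-3p detected on 2 of 4 sham arrays, so its size rests partly on values near the floor. miR-652-5p fell by 0.65 and miR-652-3p by 0.27. Differences between arms are contrasts within an array, so scaling by 1 factor per array does not move them, apart from values at the floor. Quantile normalization is not such a scaling, and the changes of single arms do move with scaling.

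Among 42 pairs of tested miRNAs whose genes lie within 10000 bases of each other, 34 had log2 changes of the same sign, called or not, and in 20 the changes of the members differed (limma, adjusted p below 0.05). Both members were called in 16 pairs, and in 3 of these they went opposite ways. miR-212-3p fell by 0.54 while its neighbour miR-132-3p rose. miR-132-3p was detected on 1 of 4 sham arrays and lay at the floor on the other 3, so neither its change nor the difference within the pair is a measured size. Their probes match chromosome 11 of mm9 from 74986954 to 74986966 and from 74987232 to 74987246. miR-188-5p rose by 0.98, whereas its neighbours miR-362-3p and miR-532-5p fell by 0.33 and 0.30. Without scaling, 1 miRNA in all was called lower, miR-192-3p. The falls of miR-212-3p, miR-362-3p and miR-532-5p were then no longer called, so none of the 3 pairs kept opposite calls. Differences within a pair are contrasts within an array, which scaling by 1 factor per array does not move, apart from values at the floor. With the main scaling, miR-188-5p minus miR-532-5p changed by 1.28 ± 0.15 (log2, SE; adjusted p = 0.00078, limma). miR-362-3p minus miR-188-5p changed by -1.31 ± 0.16 (log2, SE; adjusted p = 0.00078, limma). No explanation for these pairs was tested.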
